A study of Mus musculus with 44 samples.

How the data were processed

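RNA of mouse calvarial osteoblast cultures had been hybridised to Affymetrix arrays of types A, B and C of 1 set, 44 arrays in all (18 A, 13 B and 13 C). The 3 array types carry different probe sets and were measured on the same RNA, so they add genes and no replicates. Groups were taken from the sample titles: day 7 or day 17, and GFP-positive, GFP-negative or unsorted, each with 3 experiments, which makes 18 RNA samples in 6 groups. Unsorted RNA was on array A, and that of Exp106 also on B and C, 2 arrays that entered no fit. Nothing beyond the experiment names says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples.

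The values were intensities as deposited, 1 per probe set and array, on a linear scale in whole numbers with a lowest value of 10. How the probes were summarised and scaled before that is not given in the sources used here. The tables held 0 control probe sets, so the planned check of RNA quality by the 3' and 5' signals of control genes was not done. No build is named, so no coordinates are given.

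Within each array type the trimmed means (2%) differed by more than 10%, which under the rule set before the data were examined made quantile normalization within array type, on log2 of the intensity plus 32, the main setting, and the deposited scale an alternative. A probe set was tested if it lay above its array's median on at least 3 arrays of the fit. The series' own probe tables named 1 gene for 29131 of 36701 probe sets, several for 724 and none for 6846, and together 15964 genes. Counts are of probe sets. For named genes and lists, a gene was represented by 1 probe set, from array A before B before C and then the brightest.

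Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), to the 12 sorted samples on all 3 array types for comparisons between sorted groups and to the 18 samples on array A for comparisons with unsorted cells. Adjusted p-values are Benjamini-Hochberg over all probe sets of a comparison, called under 0.05. There were 8 comparisons: GFP-positive against GFP-negative on each day, the difference of these 2 effects, day 17 against day 7 in each of the 3 kinds of cells, and unsorted cells against the mean of the sorted fractions on each day. Of 18 gene lists written before the data were examined, those with at least 5 tested members were tested with camera at its preset correlation of 0.01, 17 in the sorted fit and 16 on array A. The list of sex-linked genes had 4 members in the probe tables and was not tested. Camera with an estimated correlation was the alternative.

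Sample titles share an experiment name between fractions, and so were taken as pairs. As a check, the correlation of the deviations of the 2 fractions from their group means on array A was 0.29, 0.50 and 0.42 in Exp99, Exp101 and Exp103 and 0.47, 0.59 and 0.67 in Exp100, Exp105 and Exp106. On array B it was 0.15, 0.11 and 0.38, and 0.27, 0.39 and 0.51. On array C it was 0.06, 0.06 and 0.02 at day 7 and 0.14, 0.15 and 0.43 at day 17. The highest correlation between fractions of different experiments was 0.167, 0.171 and 0.00252 on arrays A, B and C at day 7 and 0.559, 0.309 and 0.160 at day 17. That was above the value within the experiment for Exp99 and Exp101 on B, for Exp100 on A, B and C and for Exp105 on C, so the pairing rests on the titles. A fit with experiment as a fixed block was an alternative for comparisons within a day, and a random block, with the correlation estimated over probe sets (statmod 1.5.0), for all.

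The rule for named genes was set before the data were examined. It took, from each comparison of 2 groups, the 6 largest rises and 6 largest falls among genes that passed and whose groups did not overlap, 5 in each direction for the difference of the effects, and the 2 largest changes among the passing members of each list. It added, whatever their values, Col1a1, Col1a2, Alpl, Ibsp and Dmp1, and Fos, Jun, Egr1 and Atf3 for unsorted against sorted cells, while the remaining genes of that fixed set are not analysed here. Symbols of unnamed transcripts were passed over. Further genes were chosen after values had been seen: for GFP-positive against GFP-negative and unsorted against sorted cells at day 7, where 0 passed limma (329 and 59 at an unadjusted p under 0.05), the 6 with the smallest p in each direction and the 4 largest changes in each list that passed, and, at day 17 and for the difference of the effects, the largest changes of passed lists among genes called with the block.

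Alternatives chosen before the data were examined were pseudocounts of 8 and 128, no filter, a filter at the 75th percentile, values as deposited, a fit of only the groups compared, no variance trend, a change of at least 2-fold, each RNA sample left out in turn, and the blocks. Leaving out Exp106, with and without the block, was added after its arrays had been seen.

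The pipeline was tested on simulated data with the spread of these arrays and 200 changed probe sets per comparison. At 4-fold it called 37.9% (day 7) and 40.6% (day 17) of these, at 2-fold 4.76% and 1.54%, and at 1.5-fold 0, with 3 and 2 false calls. Most 2-fold changes of single genes would be missed. Camera called 2 of 50 unchanged lists and 50 of 50 shifted by 0.5, which leaves lists of correlated genes untested.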

Results

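The samples were primary osteoblast cultures grown from the calvaria (skull cap) of young mice that carried a type I collagen promoter fragment driving green fluorescent protein (GFP). Cells were separated by fluorescence-activated sorting into GFP-positive and GFP-negative fractions, and RNA of the unsorted culture was kept as well. Cultures taken at day 7 carried pOBCol3.6GFP and had no additions to the medium, while cultures taken at day 17 carried pOBCol2.3GFP and had received ascorbic acid and beta-glycerophosphate, the additions that let osteoblasts lay down and mineralise matrix. As background, the longer promoter fragment is active from the preosteoblast stage on and the shorter one in differentiated osteoblasts. Day, transgene and additions therefore changed together and cannot be told apart here.

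Each day was sampled in 3 experiments, named Exp99, Exp101 and Exp103 at day 7 and Exp100, Exp105 and Exp106 at day 17, and each experiment gave 1 GFP-positive, 1 GFP-negative and 1 unsorted RNA sample. All 18 RNA samples were on array A and the 12 sorted ones also on B and C, with n = 3 per group throughout. Arrays A, B and C hold 12422, 12411 and 11868 probe sets, and the trimmed mean intensity ranged from 1069 to 1766 on A, from 1367 to 1723 on B and from 1259 to 1606 on C. Changes are given on a log2 scale with their standard errors, and n = 3 limits their precision.

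The 3 RNA samples of Exp106 stood apart from all others. Its sorted samples had a mean correlation across probe sets of 0.710 with the sorted samples of the other 5 experiments on array A, against 0.894 among those others, and on B and C the values were 0.617 against 0.827 and 0.680 against 0.760. Each comparison below was repeated without it, an alternative chosen after the arrays had been seen.

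**Figure D1:**
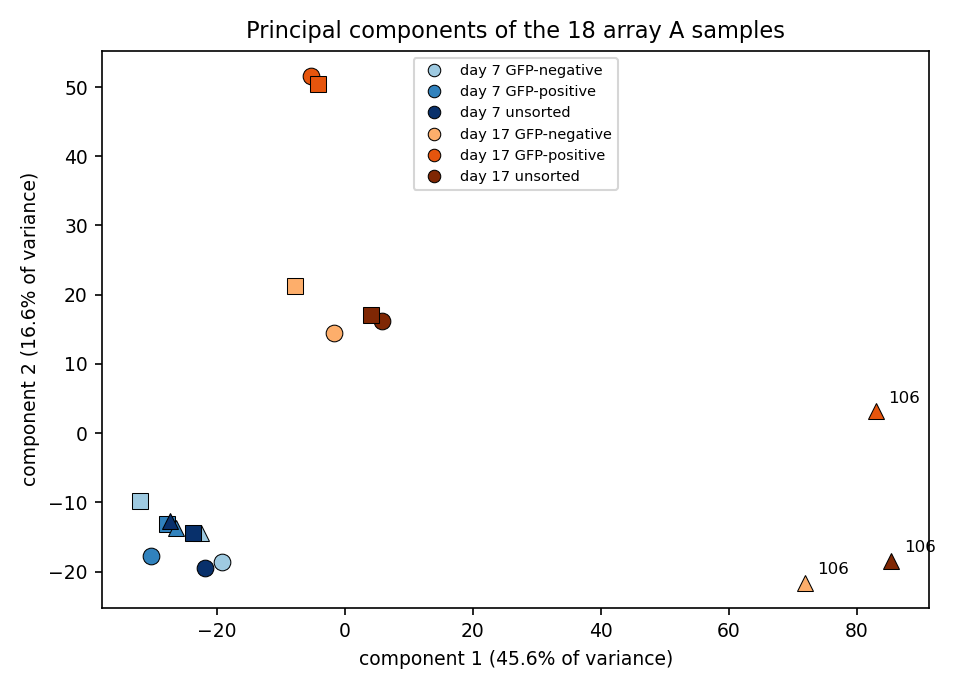
Principal components of the 18 array A samples (normalised log2 intensity of probe sets above the filter), with component 1 (45.6% of the variance) on the horizontal and component 2 (16.6%) on the vertical axis. Colour gives the group and marker shape the experiment, and the 3 samples of Exp106 lie at 71.8 to 85.4 on component 1 while all others lie between -32.0 and 5.81.

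The day 7 cultures asked which genes distinguish cells that have switched on pOBCol3.6GFP from cells that have not. Genes of macrophages and other blood cells lay lower in GFP-positive cells as a group, with a median log2 difference of -1.39 over 28 genes. Lyz2, the lysozyme of macrophages and granulocytes, had a mean normalised intensity of 577 in GFP-positive and 6588 in GFP-negative cells, a log2 difference of -3.44 ± 0.53 (SE, n = 3, adjusted p = 0.358). Ctss (a lysosomal protease of antigen-presenting cells), Mrc1 (the macrophage mannose receptor) and Tyrobp (a signalling adaptor of myeloid cells) differed by -2.83 ± 0.61, -2.89 ± 0.72 and -2.77 ± 0.65. Mrc1 lay near the pseudocount in GFP-positive cells (28.6), which sets the size of its difference (-3.58 to -1.83 over the alternatives). Skeletal muscle genes also lay lower, with a median of -0.62 over 14 genes, among them Myl1 (-2.21 ± 0.41, a myosin light chain), Tnnc1 (-2.29 ± 0.64, troponin C) and Acta1 (-1.51 ± 0.69, skeletal actin). None of these genes passed the test on its own.

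Both list shifts passed camera, at adjusted p = 7.65e-35 for macrophage and 4.89e-12 for skeletal muscle genes. With an estimated correlation the macrophage shift had adjusted p = 0.0557, the largest value over all its alternatives, and the skeletal muscle shift 0.00326. Over all genes tested 0 members of either list passed, and adjusted over the list alone 10 macrophage and 2 skeletal muscle genes were lower. Chondrocyte genes (13 genes) passed at adjusted p = 0.00516, with a median of -0.04 but a mean of -0.47, since the shift rested on Cnmd (-3.08 ± 0.81), a cartilage membrane protein, Comp (-1.32 ± 0.67) and Matn4 (-0.64 ± 0.35). It was lost with an estimated correlation (adjusted p = 0.0557), without the filter and without GFP-negative replicate Exp103 (0.0691), over a range of 0.000554 to 0.0721 among its alternatives. Endothelial genes (9 genes, median 0.23, adjusted p = 0.0181) and Wnt and BMP pathway genes (41 genes, median 0.14, adjusted p = 0.0497) lay higher. Neither held with an estimated correlation (adjusted p = 0.277 for both) or with experiment as a block (0.0572 and 0.0537), and they were lost in 8 of 16 and 10 of 18 alternatives, with adjusted p up to 0.803 and 0.574. Both were lost without GFP-positive replicate Exp99 or GFP-negative replicate Exp101, the endothelial shift also without Exp106 or GFP-positive replicate Exp103, and the Wnt and BMP shift without GFP-negative replicate Exp103. The skeletal muscle median was -0.39 without GFP-negative replicate Exp103, and the chondrocyte median -0.10 to -0.17 without any 1 sample.

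Osteoblast genes showed no shift between the day 7 fractions (26 genes, median 0.04, adjusted p = 0.869). Ibsp, the matrix protein bone sialoprotein, differed by 1.25 ± 0.90, Alpl (alkaline phosphatase) by 0.20 ± 0.37, Dmp1 (dentin matrix protein, made by osteocytes) by -0.26 ± 0.84, and the type I collagen genes Col1a1 and Col1a2 by -0.05 ± 0.34 and -0.04 ± 0.27. The other lists did not pass either, with medians from -0.12 to 0.10 and adjusted p from 0.794 to 0.894. Of these the collagen list (33 genes, median -0.05) passed in 1 of 18 alternatives, at -0.35 without GFP-negative replicate Exp101 (range of adjusted p 1.12e-06 to 0.998).

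limma called 0 of 22099 probe sets between the day 7 fractions (329 at an unadjusted p under 0.05), and with the block 0 (613). Unchanged probe sets would give 1105, so p-values ran high and 0 calls do not show equal fractions. A random block called 2, among them Myl1 (adjusted p = 0.0399). Without a filter or without a variance trend 1 probe set of Actc1, cardiac actin, was called (-4.15, adjusted p = 0.0163 and 0.0118). It was named after its values were seen. Without Exp106, which holds no day 7 sample but enters the shared spread, 4 were called, and 8 with a block. The 4 were Lyz2 (-3.47), Ctss (-2.90), F13a1 (-3.36) and 1 unnamed.

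Sorting at day 17 asked the same of cells that express pOBCol2.3GFP. GFP-positive cells carried 18.9-fold more Ptprz1, a receptor tyrosine phosphatase (log2 4.24 ± 0.46, SE, n = 3, adjusted p = 0.00105), with mean normalised intensities of 6868 against 332. Phex, an endopeptidase of osteoblasts and osteocytes that regulates phosphate, rose 17.4-fold (4.12 ± 0.46, adjusted p = 0.000425), and Col11a2, a chain of a minor fibrillar collagen, 16.8-fold (4.07 ± 0.52, adjusted p = 0.00203). Large falls were in C1qtnf2, a secreted C1q-like protein (-4.33 ± 0.54, adjusted p = 0.00151), and the complement protease C1s1 (-3.77 ± 0.40, adjusted p = 0.000663). Others were in Edil3, an integrin-binding matrix protein (-3.60 ± 0.33, adjusted p = 0.000425), and Sfrp2, a secreted Wnt modulator of fibroblasts and progenitors (-3.40 ± 0.43, adjusted p = 0.00178, mean normalised intensities 1541 against 16618).

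limma called 327 probe sets (221 genes), 78 higher and 249 lower in GFP-positive cells, and 2359 had an unadjusted p under 0.05. With experiment as a block 1112 were called (392 higher and 720 lower), which included all 327. Without Exp106 the count was 1053, and with only the groups compared 24. Leaving out 1 sample gave 778 (GFP-positive Exp106), 142 and 198 (GFP-negative Exp100 and Exp105) and 194 and 201 (GFP-positive Exp100 and Exp105). Of the 32 named genes that passed, 7 did so under every alternative. Other genes with large changes were Vit (3.50 ± 0.55), an extracellular matrix protein, Ackr3 (3.43 ± 0.44), an atypical chemokine receptor, Cox6a2 (2.98 ± 0.58), a cytochrome oxidase subunit, the long non-coding RNA Meg3 (-3.45 ± 0.35) and Clip3 (-3.38 ± 0.47). Another probe set of Meg3 had the opposite sign without being called.

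Osteoblast and osteocyte genes rose as a list (26 genes, median 0.78, adjusted p = 3.98e-05), with 3 members higher, 1 lower and the others not passing. Adjusted over the list alone, 8 rose and 2 fell, and with the block 13 rose and 1 fell among all probe sets. With an estimated correlation the list had adjusted p = 0.256. Ibsp was 2.31 ± 0.90 higher (adjusted p = 0.347, with the block 0.00412, range over the alternatives 0.00287 to 0.605) and Dmp1 2.85 ± 0.84 (adjusted p = 0.158, with the block 0.0136, range 0.00229 to 0.534). Alpl differed by 0.63 ± 0.37 (adjusted p = 0.633), Col1a1 by 0.06 ± 0.34 and Col1a2 by 0.08 ± 0.27. Col1a1 was the brightest probe set on 4 of the 18 A arrays, where normalisation between arrays fixes its value, so its change is also given on the scale as deposited (0.16 ± 0.38). Secretory pathway and endoplasmic reticulum genes rose as a list (46 genes, median 0.49, adjusted p = 1.7e-09, 0.0653 with an estimated correlation), 1 member rising on its own, 6 when adjusted over the list alone and 16 with the block. The member that rose was the chaperone Dnajb11 (0.90 ± 0.19, adjusted p = 0.041). Dnajb9 (1.26 ± 0.37), Creb3l1 (0.98 ± 0.25), a transcription factor for secretory cells, and Dnajc3 (0.95 ± 0.29) passed with the block (adjusted p = 0.011, 0.0181 and 0.0327), and Dnajb9 also without Exp106 or its GFP-negative sample and Dmp1 without Exp106 or its GFP-positive sample. The osteoblast median was 0.52 without GFP-negative replicate Exp106 and 1.39 without GFP-positive replicate Exp106.

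Fibroblast and mesenchymal progenitor genes fell as a list (28 genes, median -1.20, adjusted p = 1.21e-19, 0.00255 with an estimated correlation), and this shift passed under every alternative. Of these genes 12 fell and 0 rose, 18 fell when adjusted over the list alone and 17 with the block. Besides Sfrp2 they included Mgp, an inhibitor of calcification (-2.55 ± 0.26, adjusted p = 0.000677), and Aspn, a small proteoglycan (-2.72 ± 0.44, adjusted p = 0.0083). The median was -1.30, -1.32 and -1.17 in Exp100, Exp105 and Exp106. Smooth muscle and pericyte genes fell as a list (18 genes, median -0.60, adjusted p = 5.94e-05, 0.164 with an estimated correlation), with 4 members lower, 7 when adjusted over the list alone and 8 with the block, which also called 1 higher. Among them were Tagln, an actin-binding protein of smooth muscle (-2.34 ± 0.29, adjusted p = 0.00178), and Pdgfrb, a growth factor receptor of mural cells (-1.78 ± 0.37, adjusted p = 0.0377). Cspg4, the pericyte proteoglycan NG2, was 3.14 ± 1.21 higher and passed in blocked fits only (adjusted p = 0.333, with the block 0.0164). The smooth muscle median was -1.02 without GFP-negative replicate Exp106 and -0.20 without GFP-positive replicate Exp106.

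Macrophage genes fell as a list at day 17 as well (28 genes, median -1.17, 0 of them above 0, adjusted p = 1.7e-09, 0.256 with an estimated correlation). Coro1a, an actin-binding protein of leukocytes, was the 1 member that fell on its own (-2.20 ± 0.42, adjusted p = 0.0247), against 7 adjusted over the list alone and 5 with the block. The block added Lcp1 (-1.56 ± 0.37, adjusted p = 0.0354) and Cd52 (-1.26 ± 0.48, adjusted p = 0.0369), of which Lcp1 also passed without Exp106 or its GFP-positive sample. The fall was not shared by all experiments, since the list's median was -2.36 in Exp100, -1.64 in Exp105 and 0.29 in Exp106, and with Exp106 or its GFP-positive sample left out it was -1.95 and -1.90. These genes of another cell type moved with the fractions, and so moved beside the falls of fibroblast, smooth muscle, interferon and inflammatory genes.

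Interferon response genes (27 genes, median -0.45, adjusted p = 0.000273, 0.256 with an estimated correlation) had 3 members lower, 6 when adjusted over the list alone and 5 with the block. The first was Gbp2, an interferon-induced GTPase (-2.22 ± 0.28, adjusted p = 0.00178), followed by the immunoproteasome subunit Psmb8 (-1.85 ± 0.29, adjusted p = 0.00737). For both genes another probe set had the opposite sign and was not called. Inflammatory cytokine and acute phase genes (17 genes, median -1.63, adjusted p = 1.86e-08, 0.221 with an estimated correlation) had 3 members lower, 7 when adjusted over the list alone and 9 with the block. Cxcl12, a chemokine of stromal cells, was -3.23 ± 0.53 (adjusted p = 0.00959), the adhesion molecule Icam1 -2.79 ± 0.52 (adjusted p = 0.0219), and Ccl2, a monocyte attractant, -2.32 ± 0.66 (adjusted p = 0.14, with the block 0.0216). Wnt and BMP pathway genes (41 genes, median -0.39, adjusted p = 0.00353, 0.164 with an estimated correlation) had 1 member higher and 5 lower, against 4 and 13 adjusted over the list alone and 3 and 10 with the block. They included Ccn3, a matricellular protein (-3.31 ± 0.38, adjusted p = 0.00125), Fst, the activin inhibitor follistatin (-2.48 ± 0.38, adjusted p = 0.007), and the secreted Wnt inhibitor Sfrp1 (-2.52 ± 0.62, adjusted p = 0.0803, with the block 0.000402). Ccl2 and Sfrp1 also passed without GFP-positive replicate Exp106, where the interferon median was -0.72, and it was -0.16 without GFP-positive replicate Exp105. The Wnt and BMP median was -0.18 without GFP-negative replicate Exp100, and the inflammatory median -0.71 without the filter.

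The other 9 lists did not pass between the day 17 fractions, with medians from -0.30 for osteoclast to 0.14 for adipocyte genes and adjusted p from 0.106 to 0.961. As deposited, without normalisation between arrays, the chondrocyte list (13 genes, median 0.04, adjusted p = 0.106) had a median of -0.24 and passed at 0.0308, and it also passed with the filter at the 75th percentile (-0.95) and without GFP-negative replicate Exp100 (-0.04) or GFP-positive replicate Exp106 (-0.28). Its mean was -0.55, and camera gave it as lower throughout. The cell cycle list (49 genes, median -0.19, adjusted p = 0.254) passed as deposited at 0.0359 and without GFP-positive replicate Exp105 (-0.49) or GFP-negative replicate Exp106 (-0.68). Over their alternatives the adjusted p ranged over 0.00683 to 0.447 and 0.000146 to 0.89. Members of these lists that passed included Col8a1, a short-chain collagen (-2.88 ± 0.40), and Matn4 (-2.72 ± 0.35) and Fmod (-1.70 ± 0.25) of cartilage matrix. Others were Lpl, lipoprotein lipase (-2.33 ± 0.42), the myelin gene Pmp22 (-1.31 ± 0.28), the transcription factor Klf4 (1.69 ± 0.29) and the cell cycle inhibitor Cdkn1a (1.37 ± 0.25). Col13a1, a transmembrane collagen, rose by 2.62 ± 0.56 (adjusted p = 0.0435), a call lost in 12 of 17 alternatives (range of adjusted p 0.00172 to 0.169), among them the deposited scale, the fit without Exp106 and each fit that left out 1 of the day 17 sorted samples.

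**Figure D2:**
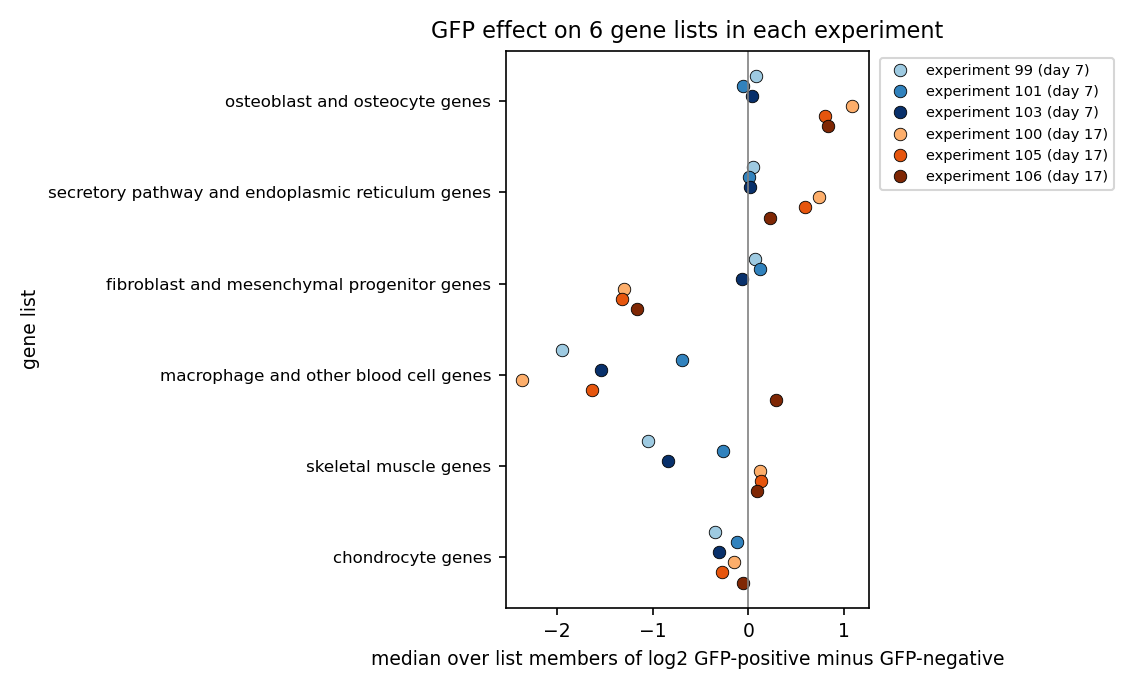
Median log2 difference between GFP-positive and GFP-negative cells over the genes of each list (vertical axis), by experiment (points), for day 7 and day 17. Macrophage genes lie at -0.69 to -2.36 in 5 experiments and at 0.29 in Exp106, while fibroblast genes lie at -1.17 to -1.32 in the 3 day 17 experiments.

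Whether the fractions differed more at one day than at the other was tested as the GFP effect at day 17 minus that at day 7. Ptprz1 differed by -0.04 ± 0.46 between fractions at day 7, where both lay near the pseudocount (mean normalised intensities 30.1 and 31.9), and by 4.24 ± 0.46 at day 17, a difference of 4.29 ± 0.66 (SE, n = 3, adjusted p = 0.0313). Phex (3.43 ± 0.65, adjusted p = 0.0337), Ackr3 (3.67 ± 0.63, adjusted p = 0.0383) and Cpe, a prohormone-processing carboxypeptidase (3.66 ± 0.62, adjusted p = 0.038), also gained in the GFP-positive fraction. These calls did not hold throughout: of 22 alternatives Phex lost its call in 15 (range of adjusted p 0.00631 to 0.125), Ackr3 in 12 (0.00073 to 0.131) and Cpe in 9 (0.00073 to 0.135), and of 17 Ptprz1 in 9 (0.00065 to 0.352). In the other direction were Egfl6, a secreted growth factor (-3.88 ± 0.56, adjusted p = 0.0115), Edil3 (-3.86 ± 0.46, adjusted p = 0.0112), Sfrp2 (-3.78 ± 0.60, adjusted p = 0.0331) and Ccn3 (-3.66 ± 0.54, adjusted p = 0.0268), of which Egfl6 and Edil3 lost the call in 1 of 22 alternatives, Sfrp2 in 10 and Ccn3 in 8. Of the 14 genes named for this difference that passed, 0 did so by limma under every alternative. For this difference limma called 56 probe sets (41 genes), 7 with a higher and 49 with a lower GFP effect at day 17, and 1353 had an unadjusted p under 0.05. With the block 253 were called, all 56 among them, and without Exp106 the count was 326. Leaving out 1 RNA sample gave 2 calls without day 17 GFP-negative replicate Exp100, 174 without day 17 GFP-positive replicate Exp106, 66 without day 17 GFP-negative replicate Exp106 and 8 to 31 without any of the other 9.

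Of the lists, fibroblast genes had the smallest p for this difference (28 genes, median difference -1.17, adjusted p = 8.51e-20, 0.00248 with an estimated correlation), with 3 members lower, 16 when adjusted over the list alone and 12 with the block. Ogn (osteoglycin) was among them at -2.71 ± 0.44 (adjusted p = 0.0331). Osteoblast genes gained (26 genes, median 0.84, adjusted p = 0.000134, 0.344 with an estimated correlation), with 1 member higher, 3 higher and 1 lower adjusted over the list alone and 5 higher with the block. Dmp1 (3.12 ± 1.19) and Ibsp (1.07 ± 1.28) did not pass, nor did Col11a2 (4.03 ± 0.73, adjusted p = 0.054, with the block 0.046 and without day 17 GFP-negative replicate Exp105 0.0293, range over the alternatives 0.00492 to 0.22). Secretory pathway genes gained (46 genes, median 0.52, adjusted p = 8.59e-08, 0.0614 with an estimated correlation) with 0 members passing. Smooth muscle genes lost (18 genes, median -0.70, adjusted p = 0.000134, 0.148 with an estimated correlation), with 2 members lower, 4 adjusted over the list alone and 3 with the block. The 2 were Tagln (-2.48 ± 0.42) and Acta2, smooth muscle actin (-1.66 ± 0.29). The smooth muscle median was -0.29 without day 17 GFP-positive replicate Exp106, and the osteoblast median 0.55 and 0.45 without GFP-positive replicate Exp105 or GFP-negative replicate Exp106 of day 17.

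Interferon (27 genes, median -0.53, adjusted p = 0.000152), inflammatory (17 genes, -1.52, 1.11e-06) and Wnt and BMP pathway genes (41 genes, -0.42, 0.000134) lost as lists too, and with an estimated correlation had adjusted p = 0.27, 0.27 and 0.0614. They had 1, 0 and 1 members lower, against 2, 5 and 5 adjusted over the list alone and 2, 4 and 4 with the block, which also called 2 Wnt and BMP genes higher. Gbp2 was -2.46 ± 0.39 (adjusted p = 0.0331), and Cxcl12 (-2.80 ± 0.74), Vcam1 (-2.15 ± 0.66), Psmb8 (-1.87 ± 0.41) and Sfrp1 (-2.11 ± 0.88) passed with the block, at adjusted p = 0.00297, 0.00473, 0.0256 and 0.0132, Vcam1 and Psmb8 also without Exp106 and Psmb8 without day 17 GFP-positive replicate Exp106 too. Skeletal muscle genes gained (14 genes, median 0.65, adjusted p = 0.00115, 0.0614 with an estimated correlation), with 0 members passing, 1 adjusted over the list alone and 2 with the block, Myl1 (2.24 ± 0.58, adjusted p = 0.0424) and Mylpf (1.76 ± 0.84, adjusted p = 0.033), of which Myl1 also passed without Exp106. Some medians moved when 1 sample was left out, to 0.39 and 1.08 for skeletal muscle genes (day 7 GFP-negative replicate Exp103, day 17 GFP-positive replicate Exp105) and to -0.35 and -0.81 for interferon genes (day 17 GFP-positive replicates Exp105 and Exp106). Without day 7 GFP-positive replicate Exp99 the inflammatory median was -0.96, and without day 7 GFP-positive replicate Exp103 the Wnt and BMP median -0.64. Macrophage genes did not differ between the days (28 genes, median 0.07, adjusted p = 0.651), although the value turned to -0.60 (adjusted p = 0.0218, range over the alternatives 0.0156 to 0.977) without day 17 GFP-positive replicate Exp106. Without day 17 GFP-positive replicate Exp100 it was 0.42 (adjusted p = 0.0156). The remaining lists had medians from -0.48 for endothelial to 0.26 for adipocyte genes and adjusted p from 0.0858 to 0.728, but some passed without 1 sample. Without GFP-positive replicate Exp105 or GFP-negative replicate Exp106 of day 17 the cell cycle list stood at -0.49 and -0.60 (range of adjusted p over its alternatives 0.000985 to 0.881). Without GFP-negative replicate Exp103 of day 7 or GFP-positive replicate Exp106 of day 17 the endothelial list stood at -0.69 and -0.74 (0.0292 to 0.48), and without GFP-negative replicate Exp101 of day 7 the collagen list at 0.29 (0.0247 to 0.907).

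**Figure D3:**
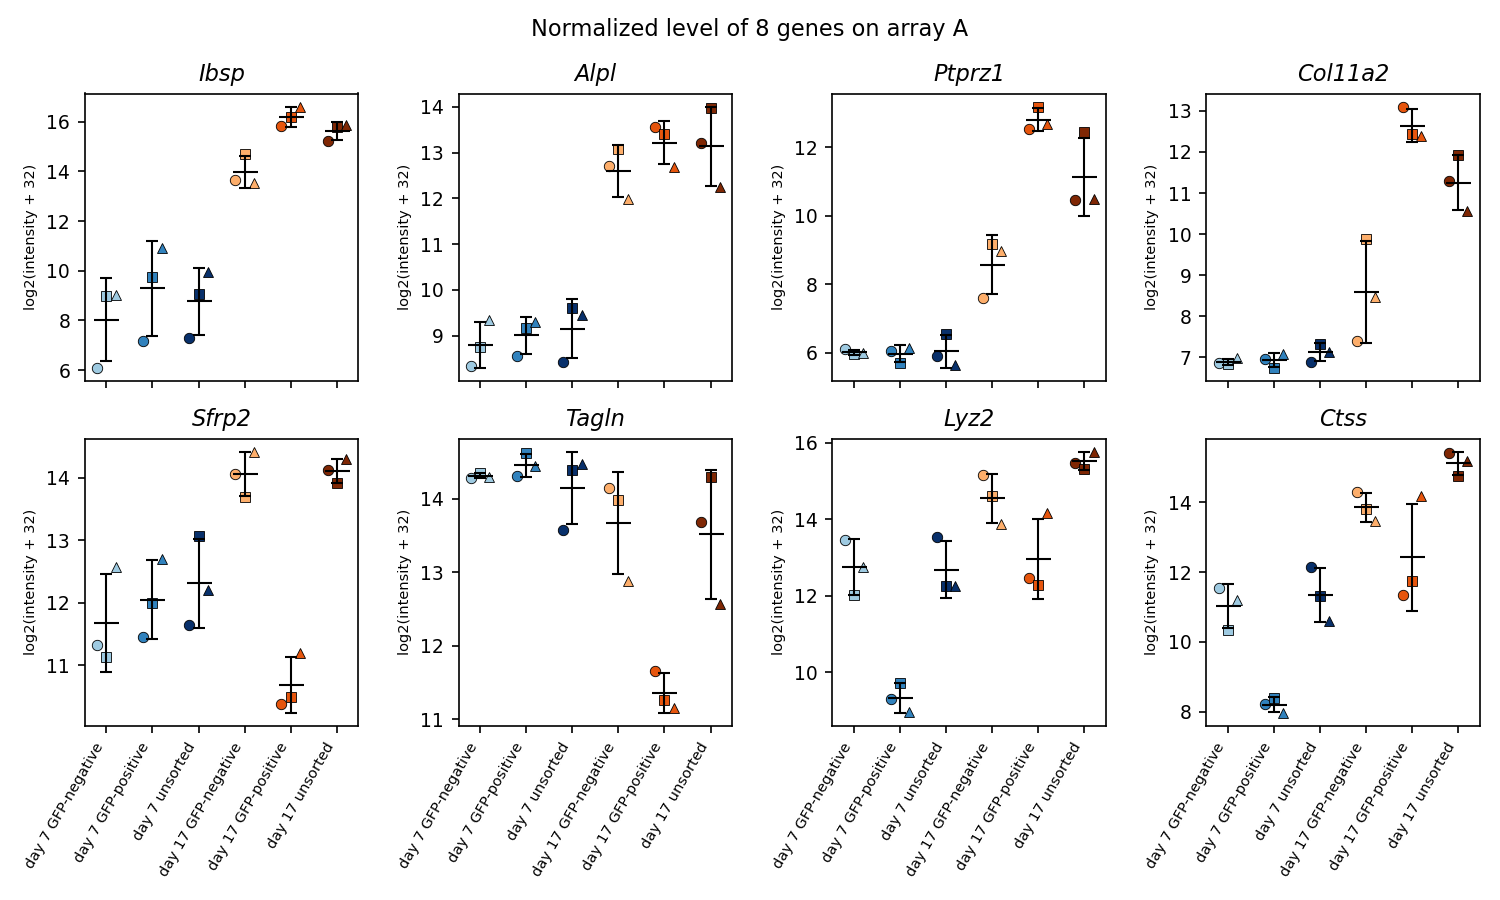
Normalised log2 intensity (vertical axis) of 8 genes on array A in the 6 groups, with a point per RNA sample, marker shape for the experiment, and bars for the mean ± SD (n = 3). Ptprz1 lies at 5.98 and 6.02 in the GFP-positive and GFP-negative fractions of day 7 and at 12.80 and 8.58 in those of day 17.

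GFP-positive cells at day 17 were next set against GFP-positive cells at day 7, a comparison in which transgene and medium changed with the day. Bone sialoprotein (Ibsp) rose by 7.00 ± 0.90 (log2, SE, n = 3, adjusted p = 0.0011), from a mean normalised intensity of 567 to 76752. Ptprz1 rose by 6.80 ± 0.46 (adjusted p = 2.38e-05, range of the log2 change over the alternatives 5.46 to 7.53), Phex 44.2-fold (5.47 ± 0.46, adjusted p = 1.71e-05), Alpl 18.8-fold (4.24 ± 0.37, adjusted p = 0.00013) and Dmp1 18.1-fold (4.18 ± 0.84, adjusted p = 0.0142, lost in 4 of 14 alternatives with adjusted p up to 0.0687). Dkk1, a secreted Wnt inhibitor, rose by 5.23 ± 0.66 and Slc36a2, an amino acid transporter, by 5.50 ± 0.70. Ptprz1, Dkk1 and Slc36a2 lay near the pseudocount at day 7 (mean normalised intensities 30.1, 34.2 and 53.0), which sets the size of their change. The deepest falls were in Rhoj, a small GTPase (-4.61 ± 0.31, adjusted p = 2.22e-05), the kinase Nrk (-4.45 ± 0.55), and Msx2, a homeobox factor of cranial bone (-4.42 ± 0.75). Next came Crabp1, a retinoic acid-binding protein (-4.37 ± 0.45), Sulf1, a heparan sulfate sulfatase (-4.33 ± 0.54), and Ccl7, a monocyte attractant (-4.30 ± 0.76).

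limma called 1205 probe sets (787 genes) between the days in GFP-positive cells, 421 higher and 784 lower at day 17, and 4260 had an unadjusted p under 0.05. Without Exp106 it called 2767, which kept 1155 of the 1205. Leaving out GFP-positive replicates Exp99, Exp101 and Exp103 of day 7 gave 533, 637 and 619 calls, and replicates Exp100 and Exp105 of day 17 gave 747 and 764. Of the 37 named genes that passed, 27 did so under every alternative.

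Osteoblast genes rose as a list in GFP-positive cells (26 genes, median 2.90, without the filter 1.67, adjusted p = 5.6e-12, 0.14 with an estimated correlation), with 15 members higher and 3 lower, 18 and 3 when adjusted over the list alone. Collagens and their processing enzymes rose (33 genes, median 0.47, adjusted p = 0.000267, 0.361 with an estimated correlation), with 5 higher and 1 lower, 9 and 1 adjusted over the list alone. Col13a1 (4.64 ± 0.56) and Col15a1 (2.63 ± 0.67, adjusted p = 0.0436, lost in 10 of 13 alternatives with adjusted p up to 0.137) were among them. Neither Col1a1 (0.84 ± 0.34, adjusted p = 0.199, as deposited 1.08 ± 0.38) nor Col1a2 (0.96 ± 0.27, adjusted p = 0.0619, as deposited 1.18 ± 0.33) passed. Secretory pathway genes rose (46 genes, median 0.62, adjusted p = 5.57e-08, 0.136 with an estimated correlation), 9 of them on their own and 16 higher and 1 lower adjusted over the list alone. Creb3l1 (1.69 ± 0.25) and the coat protein gene Copb2 (1.61 ± 0.28) rose the most. Chondrocyte genes rose (13 genes, median 0.74, adjusted p = 0.0115, 0.136 with an estimated correlation), with 2 members higher and 3 adjusted over the list alone. Col9a1 (2.01 ± 0.44) and Col11a1 (1.33 ± 0.31) were among them, and the list shift was lost in 4 of 16 alternatives, without Exp106 or its GFP-positive sample among them (range of adjusted p 0.00526 to 0.136). Its median was 0.35 in these 2 fits and without day 7 replicate Exp101.

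Macrophage genes also rose in the GFP-positive fraction (28 genes, median 1.35, adjusted p = 2.02e-08, 0.361 with an estimated correlation), with 9 members higher and 13 higher and 1 lower adjusted over the list alone. Ctss rose by 4.23 ± 0.61 (adjusted p = 0.00227) and Mrc1, near the pseudocount at day 7 (28.6), by 3.81 ± 0.72 (adjusted p = 0.0102), so genes of another cell type moved with the osteoblast genes. The list's median was 0.71 without the GFP-positive sample of Exp106 and 0.72 without Exp106, where it still passed, and 2.29 with the filter at the 75th percentile. Smooth muscle genes fell (18 genes, median -0.85, adjusted p = 0.0018, 0.335 with an estimated correlation), 5 of them on their own and 5 adjusted over the list alone, among them Tagln (-3.13 ± 0.29) and Cnn1, calponin (-2.50 ± 0.33). The smooth muscle median was -0.52 without the GFP-positive sample of Exp106. Fibroblast genes fell (28 genes, median -0.69, adjusted p = 0.0277, 0.361 with an estimated correlation), with 2 members higher and 9 lower, 3 and 11 adjusted over the list alone. Fbln2 (-3.87 ± 0.68) and Fbln5 (-2.68 ± 0.19), matrix proteins of elastic fibres, were among them. The fibroblast shift was lost in 6 of 16 alternatives, without Exp106, day 7 replicate Exp103 or day 17 replicate Exp105 among them (range of adjusted p 0.00854 to 0.361), and its median was -0.42 without the GFP-positive sample of Exp106. Interferon genes fell (27 genes, median -0.47, adjusted p = 0.0252, 0.538 with an estimated correlation), with 4 members lower and 5 adjusted over the list alone, Gbp2 (-3.31 ± 0.28) and Stat2 (-1.44 ± 0.27) among them. That shift was lost in 6 of 16 alternatives, as deposited and without replicate Exp100, Exp101 or Exp105 (median -0.12) among them (range of adjusted p 0.000143 to 0.538).

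The other 9 lists did not pass, with medians from -1.15 for inflammatory to 0.26 for adipocyte genes and adjusted p from 0.0676 to 0.835. The inflammatory list passed in 5 of 16 alternatives, at a median of -1.57 without Exp106, -1.72 without its GFP-positive sample and -1.48 without replicate Exp101 (range of adjusted p over its alternatives 0.000194 to 0.769) and the cell cycle list at 0.27 without Exp106 and 0.26 without its GFP-positive sample (0.00105 to 0.947). With all samples the cell cycle median was -0.10 and the mean -0.17, while camera gave the list as higher. Single members that changed were Ptx3, an acute phase protein (-3.74 ± 0.43), Gadd45a (-3.20 ± 0.56) and the chaperone Hsph1 (-1.97 ± 0.30) of the stress list. Others were Frzb (3.75 ± 0.80) and Bambi (3.59 ± 0.72), which restrain Wnt and BMP signals, and carbonic anhydrase Car3 (4.67 ± 0.84, from 46.9 near the pseudocount) of the adipocyte list. Cathepsin K, Ctsk (0.79 ± 0.19), and Ostm1 (-1.15 ± 0.24) of the osteoclast list and Cdc25c (0.99 ± 0.23) of the cell cycle list changed as well.

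In GFP-negative cells limma called 123 probe sets (87 genes) between the days, 62 higher and 61 lower at day 17, and 2518 had an unadjusted p under 0.05. Of the 20 named genes that passed, 6 did so under every alternative. Ibsp rose 61.3-fold here as well (5.94 ± 0.90, SE, n = 3, adjusted p = 0.0177), Alpl 14.0-fold (3.80 ± 0.37, adjusted p = 0.00129) and Wif1, a secreted Wnt inhibitor, by 3.20 ± 0.42 (adjusted p = 0.00588). Other rises were in Gpx3, a secreted glutathione peroxidase (3.26 ± 0.25, adjusted p = 0.000509), Mfap2, a microfibril protein (3.27 ± 0.28, adjusted p = 0.000509), Sema3b (3.30 ± 0.48), Matn4 (3.17 ± 0.35), the complement inhibitor Serping1 (2.57 ± 0.30) and Sfrp2 (2.41 ± 0.43, adjusted p = 0.0371). Falls were in metallothionein Mt1 (-3.02 ± 0.42, adjusted p = 0.0112), the phosphate transporter Slc20a1 (-2.79 ± 0.39), Anxa8 (-2.81 ± 0.54), and the retinoic acid-binding proteins Crabp2 (-2.49 ± 0.48) and Crabp1 (-2.45 ± 0.45). Other probe sets of Mt1 and Crabp2 had the opposite sign without being called. Dmp1 differed by 1.06 ± 0.84 (adjusted p = 0.678).

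Fibroblast genes rose between the days in GFP-negative cells (28 genes, median 0.58, adjusted p = 1.74e-08, 0.0257 with an estimated correlation), with 6 higher and 0 lower, 14 and 2 adjusted over the list alone, where they had fallen in GFP-positive cells. The test of that difference is the one given above as the difference of the GFP effects (-1.17). Wnt and BMP pathway genes (41 genes, median 0.41, adjusted p = 5.99e-06) and chondrocyte genes (13 genes, median 0.43, adjusted p = 0.000355) rose and held with an estimated correlation at 0.0257 each. Of these lists 0 and 2 members rose, against 5 and 4 adjusted over the list alone, which also gave 1 Wnt and BMP gene lower, and Fmod rose by 1.70 ± 0.25. Osteoblast genes (26 genes, median 1.37, adjusted p = 3.5e-10, 0.125 with an estimated correlation) had 3 members higher, 15 higher and 2 lower adjusted over the list alone. Collagens (33 genes, median 0.67, adjusted p = 9.45e-07, 0.178 with an estimated correlation) had 0 members passing and 1 higher adjusted over the list alone, with Col1a1 at 0.73 ± 0.34 (as deposited 0.95 ± 0.38). The collagen median was 0.28 without day 7 replicate Exp101, and the osteoblast median 0.81 without the filter.

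Macrophage genes rose as a list in GFP-negative cells (28 genes, median 1.48, adjusted p = 2.89e-12, 0.203 with an estimated correlation) with 0 members passing and 12 higher adjusted over the list alone. Genes of another cell type thus again moved with the day. Endothelial genes rose (9 genes, median 0.43, adjusted p = 0.0233, 0.229 with an estimated correlation), a shift lost without Exp106 and without replicate Exp100, Exp101 or Exp106 (range of adjusted p over its alternatives 0.00792 to 0.229). Skeletal muscle genes fell (14 genes, median -0.64, adjusted p = 0.00264, 0.08 with an estimated correlation). On its own 1 member was lower and adjusted over the list alone 3, Myl1 at -2.42 ± 0.41 (adjusted p = 0.0312). This list shift was lost without replicate Exp99 or Exp103 (range of adjusted p over its alternatives 7e-06 to 0.125). The other 9 lists had medians from -0.46 for immediate early to 0.66 for inflammatory genes and adjusted p from 0.0524 to 0.915. The inflammatory list (adjusted p = 0.0524) passed in 4 of 16 alternatives, among them the fits without replicate Exp99 (0.89) or Exp105 (0.83), over a range of adjusted p from 0.00322 to 0.66. The immediate early list passed without Exp106 or its GFP-negative sample (-0.15 in both, range 0.0438 to 0.363). Among the members of these 9 lists Cald1 (-1.44 ± 0.27) and Ostm1 (-1.34 ± 0.24) fell and Ctsk rose by 1.06 ± 0.19. Without Exp106 the cell cycle list (median 0.03, adjusted p = 0.148) passed at 0.46 (range of adjusted p over its alternatives 1.36e-09 to 0.935) and without GFP-negative replicate Exp106 at 0.48, and limma called 602 probe sets, 120 of the 123 among them. Leaving out GFP-negative replicates Exp99, Exp101 and Exp103 of day 7 gave 26, 29 and 30 calls, and Exp100 and Exp105 of day 17 gave 36 and 40.

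In unsorted cultures, which never passed the sorter, osteoblast genes rose as a list between the days (20 genes, median 1.09, adjusted p = 2.35e-07, 0.101 with an estimated correlation). Of its members 8 were higher, 2 lower and 10 did not pass, and 12 were higher and 2 lower adjusted over the list alone. Ibsp rose 116-fold (6.86 ± 0.88, SE, n = 3, adjusted p = 0.000421), Ptprz1 by 5.09 ± 0.53 (adjusted p = 0.0001) and Alpl 15.8-fold (3.99 ± 0.45, adjusted p = 0.000142). The value of Ptprz1, from 33.9 near the pseudocount, ran from 3.85 to 5.79 over the alternatives. Dmp1 rose by 3.79 ± 1.04 (adjusted p = 0.0419), a call lost in 7 of 14 alternatives, where the value ran from 2.91 to 5.35 and the adjusted p from 4.53e-05 to 0.146. Macrophage genes rose with them, as a list with all 31 members above 0 (median 2.38, adjusted p = 2.74e-24, 0.0967 with an estimated correlation), 19 of them on their own and 27 adjusted over the list alone. Ctss rose 13.6-fold (3.76 ± 0.57, adjusted p = 0.00164) and the complement gene C1qb by 3.75 ± 0.74 (adjusted p = 0.00805). Outside the list rose Cd5l, a secreted macrophage protein, by 4.84 ± 0.81, arginase Arg1, from 61.6 near the pseudocount, by 4.69 ± 0.89 and apolipoprotein Apoe, abundant in macrophages, 25.5-fold (4.67 ± 0.76, adjusted p = 0.00232). Falls were largest in Anxa8 (-3.41 ± 0.63), Msx2 (-3.32 ± 0.79), Tnnc1 (-3.32 ± 0.52, to 50.5 near the pseudocount), Crabp1 (-3.15 ± 0.51) and Acta1 (-2.82 ± 0.66).

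On array A limma called 426 of 7455 probe sets (341 genes) between the days in unsorted cells, 227 higher and 199 lower, and 1616 had an unadjusted p under 0.05. Of the 38 named genes that passed, 20 did so under every alternative. As deposited the count was 311, of which 206 (66.2%) were higher, against 53.3% of the 426. Without Exp106 it was 930, which kept 400 of the 426, and leaving out replicates Exp99, Exp101 and Exp103 of day 7 gave 178, 182 and 144, and Exp100 and Exp106 of day 17 gave 259 and 198. Fibroblast genes rose (26 genes, median 0.32, adjusted p = 0.00147, 0.0967 with an estimated correlation), 6 on their own and 6 adjusted over the list alone, with Gpx3 at 2.85 ± 0.29 and Sfrp2 3.48-fold higher, and without replicate Exp100 the median was 0.20. Chondrocyte genes rose (10 genes, median 0.62, adjusted p = 0.00068, 0.0321 with an estimated correlation), 2 on their own, Matn4 at 2.76 ± 0.38 and Fmod at 0.94 ± 0.26. Collagens rose as a list (27 genes, median 0.50, adjusted p = 0.000227, 0.244 with an estimated correlation), 2 on their own, Col13a1 at 2.40 ± 0.57 and the prolyl hydroxylase P4ha2 at 1.38 ± 0.37, while Col1a1 was 0.50 ± 0.30.

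Smaller shifts in unsorted cells passed in osteoclast (5 genes, median 0.67, adjusted p = 0.0284), neural (9 genes, 0.20, 0.0448), inflammatory (21 genes, 0.77, 0.00563) and Wnt and BMP pathway genes (31 genes, 0.24, 0.0204), all higher at day 17. With an estimated correlation their adjusted p were 0.109, 0.173, 0.437 and 0.109. On their own 0, 2, 1 and 2 members rose and 1 inflammatory gene fell, against 2, 2, 4 and 3 higher and 2 inflammatory genes lower adjusted over the list alone. Serping1 (2.49 ± 0.28), Ptx3 (-1.81 ± 0.51), Pmp22 (0.96 ± 0.25) and the synuclein gene Sncg (1.05 ± 0.23) were among those that changed. The osteoclast, neural, inflammatory and Wnt and BMP shifts were lost in 4 of 15, 8 of 15, 4 of 16 and 3 of 16 alternatives. The first 3 were lost without Exp106 or its unsorted sample, the osteoclast one also without replicate Exp100, the neural one as deposited and without replicate Exp103 or Exp105, and the Wnt and BMP one without replicate Exp105. Without the unsorted sample of Exp106 the neural median was 0.06 and the inflammatory one 0.49, without replicate Exp105 the neural one was 0.34, and without replicate Exp101 the Wnt and BMP one was 0.37. Over their alternatives the adjusted p ranged from 0.0101 to 0.109, 0.0269 to 0.352, 0.000895 to 0.437 and 0.00509 to 0.109. Skeletal muscle genes fell (13 genes, median -0.79, adjusted p = 0.00554, 0.101 with an estimated correlation), 3 on their own and 4 adjusted over the list alone, and this shift was lost with the filter at the 75th percentile as well (adjusted p = 0.0524, range over its alternatives 5.38e-06 to 0.101). The other 6 lists had medians from -0.59 for smooth muscle to 0.35 for adipocyte genes and adjusted p from 0.0619 to 0.717. Members of them that rose included the major histocompatibility genes H2-D1 (1.17 ± 0.19) and H2-K1 (0.94 ± 0.22), Creb3l1 (1.34 ± 0.26) and Car3 (2.65 ± 0.75). The adipocyte list (adjusted p = 0.0619) passed without the filter at 0.0254 (range over its alternatives 0.0254 to 0.187). The cell cycle list (median -0.16 and mean -0.17, though given as higher by camera) passed without Exp106 or its unsorted sample at 0.26 (range of adjusted p over its alternatives 0.000307 to 0.929).

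Unsorted cells were also set against the mean of the 2 sorted fractions of the same day on array A, each fraction with equal weight whatever its share of the culture. At day 7 macrophage genes lay higher in unsorted cells than that mean (31 genes, median 0.81, 29 of them above 0, adjusted p = 1.38e-27, 0.047 with an estimated correlation). Lyz2 lay at 1.64 ± 0.43, Ctss at 1.73 ± 0.50, Mrc1 at 1.95 ± 0.58 and C1qb at 2.00 ± 0.64 (SE, n = 3 against 6). Mrc1 and C1qb lay near the pseudocount in GFP-positive cells (29.3 and 31.5), which sets the size of their difference. The 2 fractions differ in these genes, so their mean lies below the higher one, and against the higher fraction the list's median was 0.23, 0.45 and -0.31 in Exp99, Exp101 and Exp103, with 21, 23 and 10 of the 31 members above it. Skeletal muscle genes (13 genes, median 0.42, adjusted p = 5.11e-05, 0.0353 with an estimated correlation) and chondrocyte genes (10 genes, median 0.15, adjusted p = 0.002, 0.0353 with an estimated correlation) lay higher too, the chondrocyte shift being lost without the filter (adjusted p = 0.137, range over its alternatives 3.32e-05 to 0.137). Collagens lay higher (27 genes, median 0.29, adjusted p = 6.94e-09, 0.164 with an estimated correlation). The collagen median was 0.11 and 0.19 without GFP-negative or GFP-positive replicate Exp101 and 0.45 without unsorted replicate Exp103, and the chondrocyte median 0.23 and 0.08 without unsorted replicate Exp99 or Exp101. None of these genes passed on its own, and adjusted over the list alone 6 macrophage genes were higher.

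limma called 0 of 7455 probe sets between unsorted and sorted cells at day 7 (59 at an unadjusted p under 0.05), and 0 with the block. Unchanged ones would give 373, so p-values ran high here too. Without a variance trend 1 probe set of Actc1 was called (adjusted p = 0.0222), and without Exp106 in a blocked fit 1 unnamed. As deposited, the median over all probe sets lay 0.12 above the sorted fractions at day 7 and 0.23 above them at day 17, so the changes here are relative to that shift. The other 12 lists had medians from -0.09 to 0.18 and adjusted p from 0.0731 to 0.833. Of these the fibroblast list (26 genes, median 0.09, adjusted p = 0.0731) passed with the block at 0.0243, with the filter at the 75th percentile and without either sorted sample of Exp103 (range over its alternatives 0.012 to 0.339). The interferon list (median 0.13) passed without unsorted replicate Exp99 or either sorted sample of Exp101 (range 0.0102 to 0.669), and the inflammatory list (0.04) without GFP-negative replicate Exp99 or unsorted replicate Exp101 (0.0171 to 0.959). Smooth muscle genes (0.03) passed without unsorted replicate Exp99 (0.0243 to 0.848) and Wnt and BMP genes (0.09) with the filter at the 75th percentile (0.0389 to 0.558). The immediate early genes Fos (-0.18 ± 0.47), Jun (0.29 ± 0.21), Egr1 (0.01 ± 0.30) and Atf3 (0.13 ± 0.26), which cell dissociation can induce, did not pass. Nor did Col1a1 (0.45 ± 0.26), Alpl (0.25 ± 0.39), Ibsp (0.11 ± 0.76) or Dmp1 (-0.27 ± 0.90).

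At day 17 the same comparison was led by macrophage genes (31 genes, median 1.81, adjusted p = 6.4e-25, 0.0842 with an estimated correlation), 8 of them higher on their own, 26 adjusted over the list alone and 25 with the block. Cd68, a lysosomal glycoprotein of macrophages, was 4.91-fold higher in unsorted cells (log2 SE 0.43, n = 3 against 6, adjusted p = 0.0205) and C1qc 2.24 ± 0.48 higher (adjusted p = 0.0327). Outside the list, the scavenger receptor Stab1 (2.69 ± 0.61, adjusted p = 0.0393), the myeloid receptor Sirpa (2.72 ± 0.62, adjusted p = 0.04), Syngr1 (2.79 ± 0.62, adjusted p = 0.0379) and, of the endothelial list, Cd93 (2.17 ± 0.34, adjusted p = 0.00662) rose. Falls were small, in the repair polymerase Polb (-1.28 ± 0.31), Srp19 (-0.96 ± 0.19), a subunit of the signal recognition particle, Cebpzos (-0.93 ± 0.21) and the RNA polymerase subunit Polr2j (-0.80 ± 0.16). Cd53 (2.83 ± 0.73), C1qb (2.44 ± 0.64) and Adgre1, the F4/80 antigen (2.40 ± 0.59), passed with the block, at adjusted p = 0.00666, 0.0106 and 0.0133, and also with the higher pseudocount and without Exp106 or its GFP-positive sample. Adgre1 also passed without GFP-negative Exp100.

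limma called 119 probe sets (95 genes) at day 17, 111 higher and 8 lower in unsorted cells, and 1073 had an unadjusted p under 0.05. With the block 920 were called (467 higher and 453 lower), all 119 included, and without Exp106 668. Fitting only the groups compared gave 1 call. Leaving out the unsorted sample of Exp100, Exp105 or Exp106 gave 7, 14 or 67, the GFP-positive one 47, 31 or 465 and GFP-negative Exp105 30. Sfrp2, Col8a1, Mgp, Gbp2, Icam1, Ccn3, Fstl1, Dusp6 and Pmp22 passed, although their unsorted values overlapped the sorted ones. Of the 23 named genes that passed, 0 did so by limma under every alternative. Against GFP-positive cells 568 were called and against GFP-negative cells 1 (blocked 1724 and 46).

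Fibroblast genes rose (26 genes, median 0.40, adjusted p = 0.000166, 0.0842 with an estimated correlation), 2 on their own, 3 adjusted over the list alone and 4 with the block. Sfrp2 lay at 1.74 ± 0.36 (adjusted p = 0.031) and Mgp at 0.94 ± 0.20 (adjusted p = 0.0343). Inflammatory genes rose (21 genes, median 0.94, adjusted p = 1.37e-05, 0.257 with an estimated correlation), 1 on its own, 5 adjusted over the list alone and 9 with the block. Icam1 rose, at 1.67 ± 0.40 (adjusted p = 0.0498), and Ccl9 (2.10 ± 0.62) and Ccl8 (1.97 ± 0.79) passed with the block and without Exp106 or its GFP-positive sample. Interferon genes rose (21 genes, median 0.38, adjusted p = 0.000214, 0.257 with an estimated correlation), 2 on their own, 5 adjusted over the list alone and 4 with the block, with Gbp2 at 1.24 ± 0.21 and H2-D1 at 0.94 ± 0.16. Wnt and BMP pathway genes rose (31 genes, median 0.37, adjusted p = 0.00436, 0.0842 with an estimated correlation), 2 on their own, 3 adjusted over the list alone and, with the block, 7 with 1 lower, among them Ccn3 (1.26 ± 0.29) and Fstl1 (0.92 ± 0.21). Smooth muscle genes rose (13 genes, median 0.41, adjusted p = 0.0148, 0.321 with an estimated correlation), 0 on their own, 1 adjusted over the list alone and 3 with the block, which included Pdgfrb (1.11 ± 0.28) and Tagln (2.01-fold, log2 SE 0.33), both called without Exp106 too, Pdgfrb without its GFP-positive and Tagln without its unsorted sample. The smooth muscle shift was lost without unsorted replicate Exp100 or Exp105 and without either sorted sample of Exp106, and the interferon shift without unsorted replicate Exp106 (median 0.10). Without GFP-negative replicate Exp105 the interferon median was 0.22. Over their alternatives the adjusted p ranged from 0.000346 to 0.321 and from 1.2e-05 to 0.257. Each list of this paragraph was lower in GFP-positive cells at day 17, so its rise here is not read as a change by sorting.

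Secretory pathway genes were higher in GFP-positive cells at day 17. In unsorted cells they lay lower than the mean of the sorted fractions (40 genes, median -0.32, adjusted p = 7.04e-05, 0.123 with an estimated correlation). This shift too is not read as a change by sorting. Of the list's members 0 passed, 0 adjusted over the list alone and 14 with the block. Among the 14 were Sec13 (-1.01 ± 0.38), Ostc (-0.92 ± 0.26) and Sec61b (-0.70 ± 0.20), at adjusted p = 0.00319, 0.00453 and 0.0118, and these 3 passed without Exp106 or its GFP-positive sample as well. Osteoblast genes did not shift (20 genes, median -0.04, adjusted p = 0.729), with Ibsp at 0.54 ± 0.76, Dmp1 at 0.89 ± 0.90, Alpl at 0.24 ± 0.39 and Col1a1 at 0.14 ± 0.26. Of the immediate early genes, Fosl1 (1.98 ± 0.38, adjusted p = 0.0205) and the phosphatase Dusp6 (1.36 ± 0.29, adjusted p = 0.0327) were higher in unsorted cells. Fos lay at -1.73 ± 0.47 (adjusted p = 0.0793, with the block 0.0149), Atf3 at 0.82 ± 0.26 (0.131, with the block 0.037), Jun at 0.57 ± 0.21 and Egr1 at 0.38 ± 0.30. Without Exp106 Fos, Atf3, Jun and, of the osteoblast genes, Dmp1 (1.63) passed, and Atf3 also without its GFP-positive sample. The other lists had medians from -0.09 to 0.36 and adjusted p from 0.0635 to 0.729. Of these collagens passed without the filter and with only the groups compared (range of adjusted p over the alternatives 0.00533 to 0.585), adipocyte genes without the filter and with it at the 75th percentile (0.0339 to 0.179), and cell cycle genes at -0.32 without either sorted sample of Exp106 (0.0278 to 0.949). Single members that rose were Col8a1 (1.71 ± 0.33) and Tcirg1, a proton pump subunit of osteoclasts (1.33 ± 0.29).

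**Figure D4:**
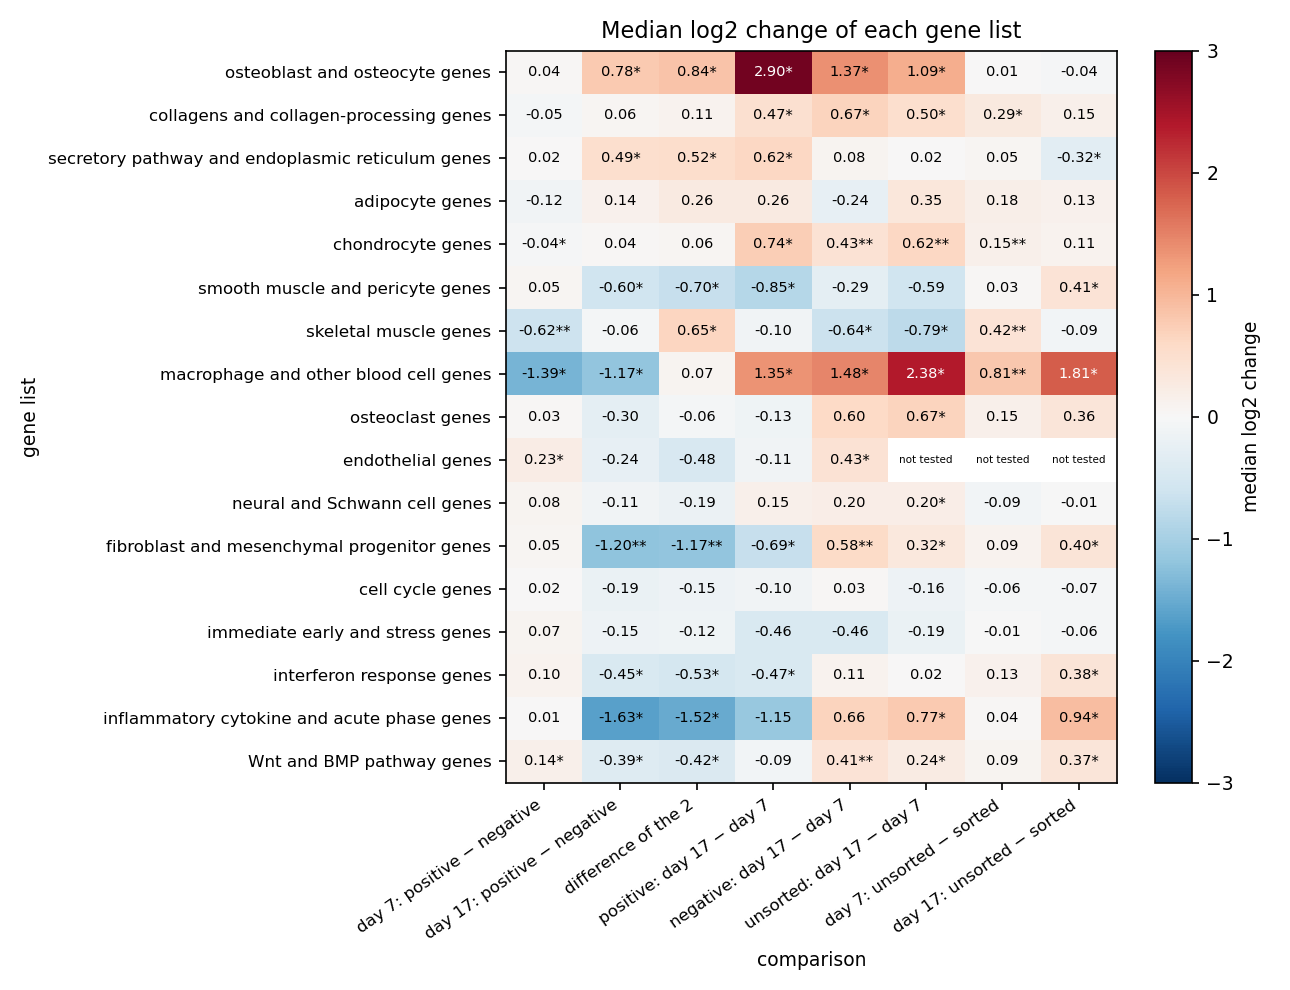
Median log2 change over the genes of each list (colour and printed value) in the 8 comparisons (columns), where * marks an adjusted p under 0.05 by camera and ** one that also held with an estimated correlation. Fibroblast genes stand at -1.20 between the day 17 fractions and 0.58 between the days in GFP-negative cells.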

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

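Of the tests below, those on macrophage genes in the Exp106 fractions and on leaving out Exp106 were chosen only after the result was seen, and the splits within experiments after the other splits had been seen. A first set of results is given because a test of the difference itself (the difference of the GFP effects, day 17 minus day 7, by limma) passed. The test asks whether GFP-positive and GFP-negative cells differed by another amount at day 17 than at day 7. The genes were Ptprz1 (4.29), Ackr3 (3.67), Cpe (3.66) and Phex (3.43), with more signal in GFP-positive cells at day 17, and Egfl6 (-3.88), Edil3 (-3.86), Sfrp2 (-3.78), Clip3 (-3.68), Ccn3 (-3.66), C1s1 (-3.54), Ipo13 (-3.53), Col8a1 (-3.44), Meg3 (-3.32), Ogn (-2.71), Tagln (-2.48), Gbp2 (-2.46) and Acta2 (-1.66), with less. The lists, by camera, were osteoblast (median 0.84), secretory pathway (0.52) and skeletal muscle genes (0.65), and inflammatory (-1.52), fibroblast (-1.17), smooth muscle (-0.70), interferon (-0.53) and Wnt and BMP pathway genes (-0.42). With an estimated correlation fibroblast genes alone held (adjusted p = 0.00248), and the other 7 lists had adjusted p from 0.0614 to 0.344. Day, transgene and medium additions changed together, so the design does not tell which of them made the difference.

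The first pattern weighed was that Exp106 stood apart on all its arrays. Its offset from the other day 17 experiments had an SD of 1.06 on array A, against 0.32 between Exp105 and Exp100, and 31.3% of probe sets lay beyond 2-fold, against 1.38%. A biological difference of the culture as the whole cause was argued against, since over 4284 pairs of probe sets of 1 gene the offset correlated by 0.113 where the day effect correlated by 0.505. A difference that depends on signal level alone was argued against too, as a smooth curve on level took up 0.134% of the variance. What stays open is a measurement difference specific to single probe sets, such as array lot or labelling, which may account for most of the offset (ratio of the 2 correlations 0.224, 95% interval 0.164 to 0.285), with a smaller biological part untested.

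The second pattern was that macrophage genes at day 17 lay higher in unsorted cells than in both sorted fractions. A culture that is a mixture of the 2 fractions and nothing else was argued against, because the median of unsorted minus the higher fraction was 0.84, 1.35 and 0.82 in the 3 experiments (lowest 0.818). Quantile normalization was argued against as well, with a lowest median of 0.912 on the deposited scale. Whether macrophages were in part left out of both fractions by the sort stays open, because the count run for it, at least 28 of 31 members above the GFP-negative fraction in each experiment, restates the pattern. Sorting gates are not described here, and RNA change during sorting and a biological explanation were not tested.

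The third pattern was that macrophage genes were not lower in the GFP-positive fraction of Exp106, unlike in the other 2 experiments of day 17. An exchange of its 2 fractions was argued against, since the osteoblast list was higher in its GFP-positive fraction (median 0.830) and the fibroblast list lower (-1.17). Whether macrophages were in that GFP-positive fraction stays open, since the count of 24 of 28 members with a higher difference in Exp106 than in both other experiments (38.6% of all genes) restates the pattern. Sorting for GFP would remove cells without the transgene's signal, and no biological explanation was tested.

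Other splits of the same samples were fitted to ask whether they give as many calls. For GFP-positive against GFP-negative and for the comparisons between days, 3 against 3 samples make 10 splits, too few for a share under 0.05. There the real values were 0, 327, 1205, 123 and 426 and the highest of the other splits 1, 3, 0, 1 and 0, for day 7, day 17, and the day effect in GFP-positive, GFP-negative and unsorted cells. In each of the last 4 comparisons 1 of 10 splits gave as many. At day 7 the real value by limma was 0 (329 probe sets at an unadjusted p under 0.05), which every split reaches, so that 10 of 10 says nothing. For the difference of the effects, 12 of 100 splits gave as many as the real 56 (highest other 132), so chance cannot be excluded by this count, and all 12 kept the real division of the day 17 samples. For unsorted against sorted cells at day 7 the real value by limma was 0 as well (59 at an unadjusted p under 0.05, highest other 19), so that 100 of 100 says nothing. At day 17, 8 of 100 splits gave as many as the real 119, so chance cannot be excluded by this count. These splits exchange samples across experiments and so ignore the pairing, and the highest other, 4133, set the 3 samples of Exp106 against the rest, which points to a structure by experiment. Splits within experiments only were fitted with experiment as a block. For unsorted against sorted cells at day 17, 5 of 100 drawn gave as many as the real 920, so chance cannot be excluded there either. The other 4 set the 3 GFP-positive samples against the rest (highest 1613), which is another division of the design, and no further split passed 424. For the difference of the effects, 6 of all 32 gave as many as the real 253 (highest other 325), each with the real division at day 17.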

How the results depend on the processing

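The fits without Exp106 were chosen only after its arrays had been seen, and the others before the data were examined. Counts of called probe sets moved by more than 1.5 times as follows, and the cause was not tested unless stated. With experiment as a replicate block, day 17 GFP-positive against GFP-negative gave 1112 (327 without), the difference of the effects 253 (56), and unsorted against sorted cells at day 17 gave 920 (119). A random block gave 1317, 332 and 824 for these, and 2 at day 7. The fixed block also cost the endothelial and Wnt and BMP lists at day 7 and gained the fibroblast list in unsorted against sorted cells at day 7. It gained 36 of 188 gene calls, lost 0 and changed no other call. A fixed block was not possible between days because each experiment lies in 1 day. Without Exp106 the counts were 4 (day 7), 1053 (day 17), 326 (difference), 2767, 602 and 930 (day effect in GFP-positive, GFP-negative and unsorted cells) and 668 (unsorted against sorted, day 17), and with the block as well 8, 1897, 859, 1 (unsorted against sorted, day 7) and 941. By construction, leaving out Exp106 removes its offset from the spread within groups. Fitting only the groups compared leaves fewer degrees of freedom and takes the spread from them alone. It gave 24 (day 17), 542, 42 and 214 (day effects, same order) and 1 (unsorted against sorted, day 17). No filter gave 1 (day 7) and 67 (unsorted against sorted, day 17), and no variance trend 1 in each comparison at day 7.

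Leaving out 1 RNA sample gave, from lowest to highest, 0 to 0 by limma at day 7 (329 at an unadjusted p under 0.05 with all samples), 142 (without GFP-negative Exp100) to 778 (without GFP-positive Exp106) at day 17, 2 (GFP-negative Exp100) to 174 (GFP-positive Exp106) for the difference, 533 (Exp99) to 1487 (Exp106) in GFP-positive, 26 (Exp99) to about 1.0e+02 (Exp106) in GFP-negative and 144 (Exp103) to 402 (Exp105) in unsorted cells between days, and 0 to 0 (59 at an unadjusted p under 0.05) and 7 (unsorted Exp100) to 465 (GFP-positive Exp106) for unsorted against sorted cells. The macrophage list in the difference of the effects, 0.07 with all samples, ran from -0.60 without GFP-positive Exp106 of day 17, where the direction by camera reversed, to 0.43 without GFP-positive Exp105. Other medians changed sign where a call was gained or lost while camera kept its direction. They were the cell cycle list between days (-0.10 to 0.27 in GFP-positive and -0.16 to 0.26 in unsorted cells without Exp106), the chondrocyte list at day 17 (0.04 to -0.24 as deposited) and the neural list in unsorted cells (0.20 to -0.0039 without the filter).

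Of 133 list results, 48 were lost with an estimated correlation and 3 lost and 2 gained as deposited. Of 290 gene results, 26 were lost and 2 gained as deposited, 35 lost without the filter and 16 without the trend, and of 236, 75 were lost and 1 gained with only the groups compared. The filter at the 75th percentile left a value for 224 genes and 117 lists and none for the rest. Signal over background limits the dim genes: Ptprz1 lay near the pseudocount at day 7, so its fold is understated.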

Other observations

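Single genes in unsorted cells at day 17 lay outside both sorted fractions, in comparisons chosen after the values were seen. With the block limma called 22 probe sets against each fraction with the same sign (18 above and 4 below both), and without it 1. The 0 calls in 20 simulated draws set no chance level, since all groups were unchanged there. No list was tested here, and 1 of the 22, Cyba, was on the macrophage list. With the block they included Cd93 (2.63 above the GFP-positive and 1.70 above the GFP-negative fraction), the lysosomal genes Lipa (1.96 and 1.63), Psap (1.73 and 1.35) and Ctsd (1.68 and 0.96), and the phagocyte oxidase subunit Cyba (1.52 and 0.77), and also Qk, Tpd52, Skap2, Slc20a1 and Rasa4. Fosl1 lay 1.87 and 2.08 above, and Pstk, Srsf3, Psmd14 and Ppic below both.

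The hypotheses that follow rest on tests of which those without Exp106 were chosen only after the result was seen. A first hypothesis is that the day 17 transgene marks cells that mature along the osteoblast line while the cells without it keep a fibroblast program, which may be why fibroblast genes fell between the fractions in all 3 experiments and why 1112 probe sets were called with the block. Sorting both transgenes at 1 day would test it, since day and transgene cannot be told apart here. A second hypothesis is that pOBCol3.6GFP at day 7 excludes macrophages, as the calls without Exp106 (4 probe sets, Lyz2, Ctss and F13a1 among the named) might suggest.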
